A study of Mus musculus with 8 samples.

How the data were processed

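Cortex of 2 control and 2 mutant male mice at postnatal day 34 was assayed by ribosome profiling and by poly(A) RNA sequencing, giving 8 libraries in 4 groups of 2 (RPF and RNA, control and mutant). Group and replicate number come from the sample labels. The deposited values are whole-number counts of reads per gene symbol, 1 table per library, with 24421 genes and 5 summary lines each. Per the submitters' processing notes the tools were Trim Galore 0.4.3, cutadapt 1.12, Bowtie2 2.2.5, SAMtools 1.5, HTSeq 0.6.0 and DESeq, with the mouse build mm10 (GRCm38). Those notes give no order or settings, so the part of each gene that was counted, the strand setting, the annotation release and the handling of multiply mapped reads are not given in the sources used here. Footprints are short, and reads shared by gene copies or by overlapping genes could be lost or assigned to either copy, which bears most on histone, ribosomal protein and small RNA genes and on genes with processed pseudogenes. Whole-gene counts also mix footprints before and after a selenocysteine codon with any in the untranslated regions.

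The summary lines were left out of library sizes and tests. Reads in no gene made up 29.4% to 39.4% of all counts in the RPF tables and 52.5% to 57.8% in the RNA tables, ambiguous reads 0.545% to 0.829%, and the other 3 summary lines were 0 throughout. Of the genes 910 had no count in any library. Gene counts per library ran from 7888685 to 23681528 in RPF and from 30051206 to 32379648 in RNA, and mutant RNA library 1 had counts for 20475 genes against 22156 to 22314 in the other RNA libraries. Floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate libraries were compared before averaging: none held identical values, and the chi-square of their counts per degree of freedom lay between 9.39 and 22.4, far above sampling noise, with Spearman correlations across genes of 0.979 to 0.990. Each was therefore kept as its own replicate.

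Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, robust dispersion estimates, quasi-likelihood F test, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. RPF and RNA were each fitted alone on their 4 libraries. Translational efficiency was tested as the interaction of assay and genotype in 1 fit of all 8 libraries, and the same fit gave the ratio of RPF to RNA in controls. Standard errors are the absolute log2 fold change divided by the square root of F. Printed levels are CPM on TMM-scaled library sizes, and the log2 CPM behind plots and directions used a prior count of 2. DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as other tools. With 2 mice per group the residual degrees of freedom are few, so calls lean on the spread shared across genes.

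A total of 32 gene lists were fixed before the data were examined, as were the design, most alternatives and the rule for named genes. Of these 31 had a gene in the files, and 30 had at least 3 tested genes; the list of mitochondrially encoded genes had 0 in the files and red blood cell genes had 1 tested. The selenoprotein lists are textbook lists, not chosen on these samples, and Selenov is not listed in the files. UGA positions were read from GENCODE coding sequences on GRCm38, and 24027 of the 24421 symbols matched that annotation, 651 through an older symbol. Lists were tested with camera, which asks whether a list moves more than other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. In the 3 genotype comparisons no list passed adjustment with an estimated correlation or with fry. In the simulated counts described below, a list of 20 lowered genes had unadjusted p of 0.0181 and 0.0169 in RPF (camera, estimated correlation). The values were 0.00841 and 0.00988 in RNA. Adjusted over 30 lists, even such a list could therefore fail that test in RPF and RNA. In translational efficiency the lowered list had unadjusted p of 0.00085 and 0.000806 (camera, estimated correlation), low enough to pass adjustment over 30 lists. Its median log2 changes there were -0.633 and -0.654. For lists lowered by that much, this limit of the test does not extend to translational efficiency. A list's median, mean and camera direction can differ in sign: in RPF this was so for 8 lists that did not pass, and in RNA for the late-UGA and dentate lists. It was also so in translational efficiency for stress response and thyroid genes, and in the control ratio for late-UGA, small non-coding RNA, oligodendrocyte precursor, choroid plexus and thalamic lists, none of them called. Camera compares the gene-wise test statistics of a list with those of other genes and so need not follow the median. Early and late UGA lists were compared by an exact permutation test across genes.

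Per genotype comparison the text names Secisbp2 and tested selenoproteins, up to 10 passing genes per direction with both mutants on the same side of both controls, the up to 4 members of each list with the smallest p, list members that passed, and, where fewer than 5 genes passed in a direction, the 5 with the smallest p. Genes named outside that rule are said to have been chosen after their values were seen; Camk2a and its neighbours on chromosome 18 were looked up because they lie beside Slc6a7. Some genes that the rule names are not reported here.

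The design text gives 4 mice for both assays, so replicate numbers were read as pairing the RPF and RNA libraries of 1 mouse. The difference between replicates correlated across 13705 genes at 0.356 between RPF and RNA of controls and 0.146 in mutants. Between groups of different genotype, which share no mouse, the correlation ran from -0.287 to -0.0701, in size above the mutant value for some pairs. The mutant value is therefore weak evidence of pairing. The fit with the mouse as a block was an alternative for translational efficiency. Control and mutant mice are different animals, so numbers do not pair them.

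The procedure was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed at each of 2 fold sizes. With the dispersion taken from the trend, 79% of 2-fold and 98% of 4-fold changes were recovered in RPF (14978 genes), 84% and 99% in RNA (17119 genes), and 59% and 98% in translational efficiency (17461 genes), with 8 false calls among 189, 5 among 199 and 2 among 162. With a dispersion of its own for each gene recovery was 75% and 98% (14975 genes), 91% and 99% (17115 genes), and 55% and 92% (17444 genes), but false calls rose to 32 of 211, 36 of 234 and 16 of 164, above the share set by the threshold. Simulated genes were independent, so these figures say nothing of shared variation among real genes. Alternatives covered RLE scaling, library totals, no filter, a mean count of 50, DESeq2, limma-voom, non-robust estimation, a threshold of 0.1, removal of small RNA and histone genes, a joint fit, blocks, and leaving out each library. Leaving out one library leaves a lone library in its group, which is assumed to vary like the others. Coordinates are those of GRCm38.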

Results

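Ribosome footprints (RPF, the mRNA fragments protected by translating ribosomes) and poly(A) RNA were sequenced from the cerebral cortex of 4 male C57BL/6 mice at postnatal day 34. Both mutant mice carried one floxed and one R543Q allele of Secisbp2 together with a Camk-Cre transgene, and both control mice carried wild-type alleles without Cre. Secisbp2 (SBP2) binds the SECIS element in the 3′ untranslated region of selenoprotein mRNAs and is needed to decode UGA as selenocysteine instead of stop. The labels give 2 mice per genotype and 8 libraries in 4 groups. Genotype and Cre status went together in every mouse, so an effect of the alleles and one of the transgene could not be separated. Gene counts totalled 7888685 and 9761127 in the control RPF libraries and 23681528 and 11612837 in the mutant RPF libraries. They totalled 31798058 and 30303805 in control RNA and 30051206 and 32379648 in mutant RNA. A gene needed 3 counts, or between 0.0927 and 0.380 CPM (counts scaled by library size) depending on the library, to lie above the floor that a count of 0 allows.

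Secisbp2 itself (chromosome 13, 51651697 to 51684044, GRCm38) was measured first in every library. Its footprints stood at 21.9 and 22.4 CPM in the control libraries and at 17.2 and 15.7 CPM in the mutant libraries, a mutant mean of 74.5% of control. Its mRNA stood at 19.5 and 20.9 CPM in controls and 18.03 and 14.5 CPM in mutants, 80.5% of control. Both mutant libraries lay below both control libraries in each assay. The Secisbp2 log2 fold change was -0.42 ± 0.17 (SE, n = 2 per group) in RPF and -0.31 ± 0.13 in RNA, with unadjusted p of 0.0355 and 0.0516, and neither passed adjustment over all genes (edgeR, adjusted p = 0.968 in RPF). Counts of the whole gene cannot tell the floxed exons or the missense allele from the rest of the transcript.

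The first comparison asked how footprints on selenoprotein and other mRNAs differed between mutant and control cortex. Footprints of the glutathione peroxidase Gpx1, an early-responding selenoenzyme under low selenium, stood at 51.9 ± 12.05 CPM in controls and 17.0 ± 0.128 CPM in mutants (SD, n = 2), 32.8% of control, a log2 change of -1.60 ± 0.19. Gpx4, the glutathione peroxidase that reduces lipid hydroperoxides, fell by 1.14 ± 0.18 on the log2 scale, and Selenow (Sepw1 in the files), an abundant small selenoprotein of brain, fell by 0.91 ± 0.17. The endoplasmic reticulum selenoproteins Selenof (Sep15) and Selenom (Selm) changed by -0.67 ± 0.12 and -0.88 ± 0.20. Selenoh (2700094K13Rik), a nucleolar selenoprotein, fell by 1.35 ± 0.38, the secreted Gpx3 fell by 1.22 ± 0.36 and the mitochondrial thioredoxin reductase Txnrd2 fell by 0.67 ± 0.21. These 8 of the 21 selenoproteins tested passed when p-values were adjusted over the list alone (edgeR, adjusted p from 0.000347 for Gpx1 to 0.030 for Txnrd2), with both mutant libraries below both controls for each, and none rose. The other 13 did not pass, among them the cytosolic thioredoxin reductase Txnrd1 at 100.3% of control. Of the 21, 17 had a lower estimate in mutants. Under the alternative that required a mean count of 50, 18 selenoproteins were tested and 6 passed over the list alone. Selenoh and Gpx3 were not tested under that filter, so their calls rest on low footprint counts.

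**Figure D1:**
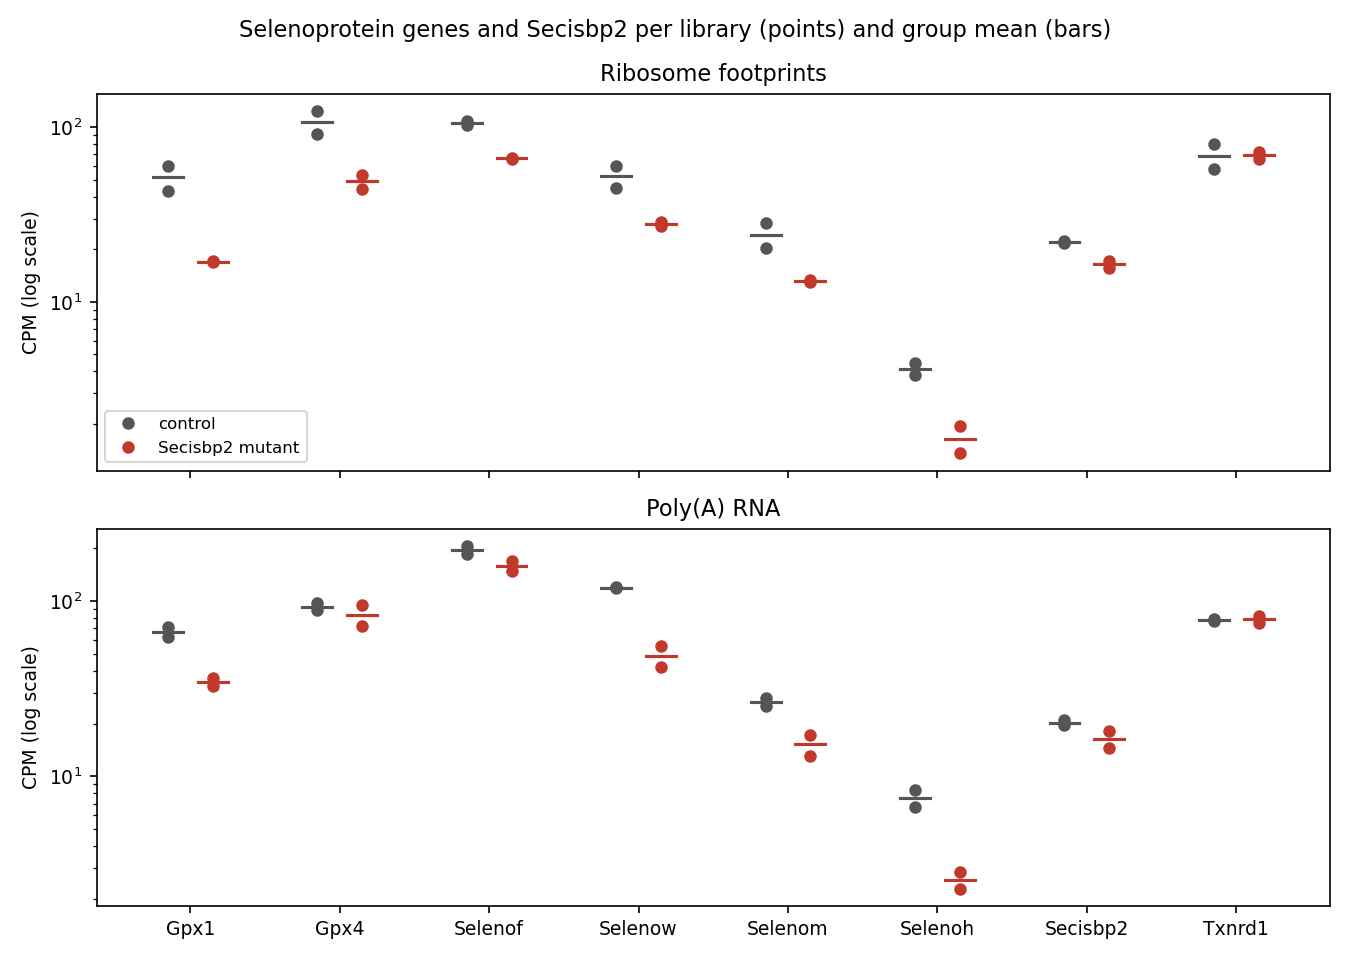
CPM (log axis) of 8 genes in each library, points for single libraries and bars for the group mean (n = 2), RPF and RNA of control and mutant cortex. Gpx1 footprints lie at 17 CPM in both mutant libraries against 43 and 60 CPM in controls, while Txnrd1 overlaps between genotypes.

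Over all 15196 genes tested in RPF, 0 passed (edgeR, Benjamini-Hochberg), with 701 at an unadjusted p below 0.05 against 760 by chance. DESeq2 called 25 genes, 4 of them selenoproteins, limma-voom called 0, and a single fit of all 8 libraries called Gpx1 and Slc6a7. Leaving out one library gave 7 calls without control RPF library 1, 13 without control RPF library 2, 16 without mutant RPF library 1 and 21 without mutant RPF library 2. The 8 selenoproteins passing over the list alone became 5 without control RPF library 1 or without mutant RPF library 1, 5 with DESeq2, and 11 without control RPF library 2. As a set, selenoprotein footprints were lower than those of other genes, with a median log2 change of -0.32 (camera with preset correlation, adjusted p = 1.1e-15). That call was lost with an estimated correlation (adjusted p = 0.486 with an estimated correlation), and the median was -0.59 without control RPF library 2.

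Selenoproteins were also divided by where the first selenocysteine UGA lies. Of the 14 tested with the UGA early or inside the coding sequence, 7 fell when adjusted over the list alone (5 without control RPF library 1 or mutant RPF library 1), and the median was -0.59 (camera, adjusted p = 4.5e-21; adjusted p = 0.486 with an estimated correlation). Of the 7 with the UGA close to the stop codon, the thioredoxin reductases among them, 0 passed over that list alone and the median was -0.043 (camera, adjusted p = 0.443). Txnrd2, a member of this late list, was nevertheless lower and passed when adjusted over the full selenoprotein list. The mean log2 change was -0.68 ± 0.52 (SD across genes) for the early list and -0.11 ± 0.30 for the late list, a difference of -0.56 (exact permutation across genes, two-sided p = 0.0173). Genes are not independent replicates. The list called early also holds genes with the UGA further in, such as Selenof (Sep15) at 57.4%, Selenon (Sepn1) at 76.8% and Msrb1 at 81.9% of the coding sequence. In Gpx1 the UGA is codon 47 of 201 (chromosome 9, 108338903 to 108340343, GRCm38), in Gpx4 codon 73 of 197 (chromosome 10, 80047166 to 80056439), and in Selenow (Sepw1) codon 13 of 88 (chromosome 7, 15917208 to 15922402). In Txnrd2 it is codon 526 of 527 (chromosome 16, 18426384 to 18479073).

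**Figure D2:**
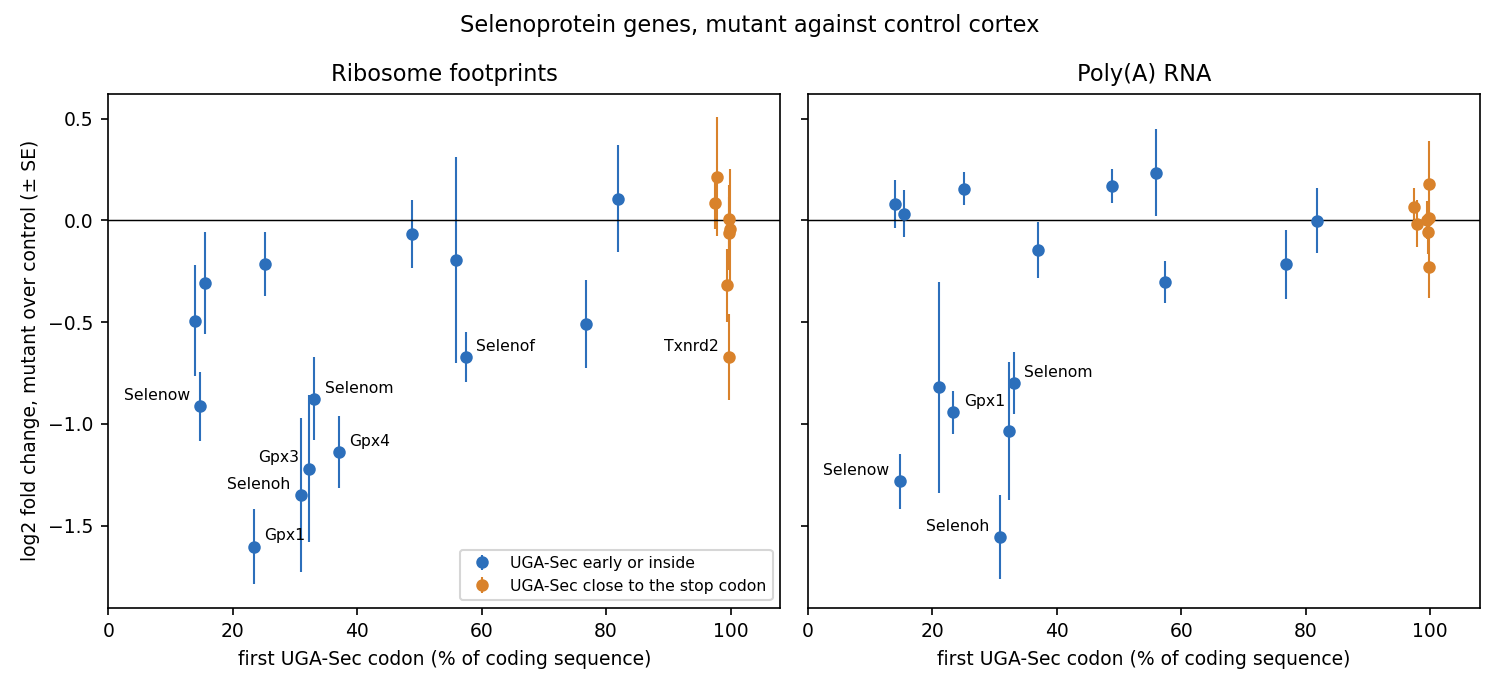
Log2 fold change of mutant over control (± SE, n = 2 per group) of each selenoprotein against the position of its first UGA codon as a percentage of the coding sequence, RPF and RNA in separate panels, with genes passing over the list alone named. In RPF the mean change is -0.68 for genes with the UGA early or inside the coding sequence (blue). It is -0.11 for those with the UGA close to the stop codon (orange).

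Footprints of microglia markers were higher in mutant cortex. Of 20 such genes, 18 had a higher estimate and 12 rose when adjusted over the list alone, 0 over all genes; the median log2 change was 0.56 (camera, adjusted p = 1.1e-22; adjusted p = 0.486 with an estimated correlation). The purinergic receptor P2ry12 rose by 0.86 ± 0.16, the fractalkine receptor Cx3cr1 by 0.67 ± 0.13 and the lipid-sensing receptor Trem2 by 1.03 ± 0.22 (SE, n = 2 per group). Without mutant RPF library 2, 6 passed over the list alone. Striatal neuron markers were higher too, with 10 of 10 estimates up, 5 passing over the list alone and a median of 0.42 (camera, adjusted p = 2.5e-14; adjusted p = 0.486 with an estimated correlation). They included the adenosine receptor Adora2a at 0.92 ± 0.18, the dopamine receptor Drd1 at 0.77 ± 0.16, the enkephalin precursor Penk at 0.90 ± 0.20 and the phosphodiesterase Pde10a at 0.40 ± 0.11. The striatal median was 0.83 with 9 passing without control RPF library 1, and 3 passed without mutant RPF library 1. Endoplasmic reticulum chaperone and unfolded protein response genes had a median of 0.19 over 20 genes (camera, adjusted p = 1.8e-05; adjusted p = 0.486 with an estimated correlation), though 0 passed over the list alone. The disulfide isomerase Pdia4 was at 0.41 ± 0.12, the lectin chaperone Canx at 0.37 ± 0.11 and the chaperone Hsp90b1 at 0.40 ± 0.12.

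**Figure D3:**
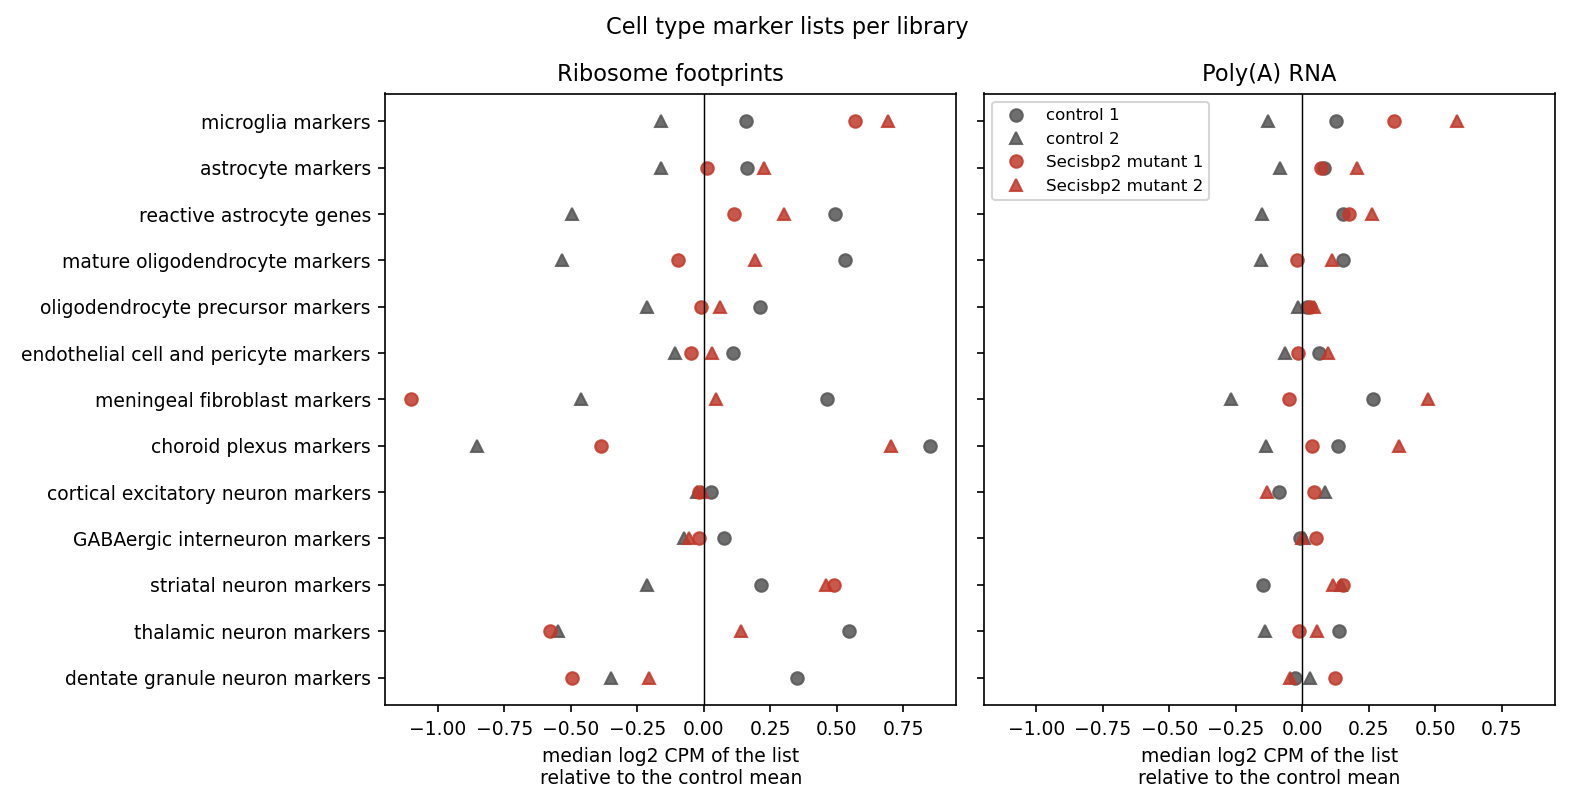
Median log2 CPM of each of 13 cell-type marker lists in each library, relative to the mean of the control libraries of the same assay, with RPF and RNA in separate panels. Microglia markers lie above both controls in the mutant libraries of both assays, with a median gene-wise log2 change of 0.56 in RPF and 0.43 in RNA.

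Another 6 lists passed in RPF with the preset correlation but hung on single libraries, and each was lost with an estimated correlation (adjusted p = 0.993 with an estimated correlation, or 0.486 for cholesterol synthesis). Meningeal fibroblast markers had a median of -0.60 (camera, adjusted p = 0.0029), 7 of 8 lower, and prostaglandin D synthase Ptgds at -1.06 ± 0.27 and the GABA transporter Slc6a13 at -0.75 ± 0.22 passed over the list alone. That median was 0.073 without control RPF library 1, -0.086 without mutant RPF library 1, -0.99 without control RPF library 2 and -1.18 without mutant RPF library 2, where 1, 1, 0 and 4 genes passed; the 1 without control RPF library 1 was higher in mutants and the others lower. Cytosolic ribosomal proteins had a median of 0.15 (adjusted p = 4.3e-05; 58 of 77 higher, Rps13 at 0.49 ± 0.14), which was 0.056 without control RPF library 2 and 0.23 without control RPF library 1. NRF2 targets had a median of 0.11 (adjusted p = 0.0188; the peroxiredoxin Prdx1 at 0.51 ± 0.12), which was 0.0045 without control RPF library 2, 0.046 without mutant RPF library 2, 0.27 without control RPF library 1 and 0.20 without mutant RPF library 1. Cholesterol synthesis genes had a median of 0.10 (adjusted p = 0.0148), and the call was lost without control RPF library 2 (0.080) or mutant RPF library 2 (0.094). Astrocyte markers had a median of 0.15 (adjusted p = 0.0272), which was 0.31 and 0.24 without library 1 of control and mutant RPF and -0.051 and -0.00014 without library 2. Small non-coding RNA genes had a median of -0.14 over 220 genes (adjusted p = 0.0148), which was -0.44 and -0.51 without library 1 of control and mutant RPF, 0.32 and 0.018 without library 2, and lost its call with library totals in place of TMM (adjusted p = 0.0554).

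The remaining 19 of the 30 lists tested in RPF did not pass (camera, adjusted p from 0.0651 to 0.982). Hippocampal dentate granule neuron markers had a median log2 change of -0.33 over 5 genes and thalamic neuron markers -0.30 over 6, all members with lower estimates. The medians were -0.11 for selenocysteine synthesis and incorporation factors, 0.086 for integrated stress response genes, -0.023 for antioxidant enzymes without selenocysteine, -0.053 for thyroid hormone responsive genes, 0.034 for immediate early genes and 0.023 for synaptic genes. They were -0.021 for nonsense-mediated decay factors, 0.017 for nuclear-encoded respiratory chain subunits and -0.021 for replication-dependent histone genes. Among cell types the medians were -0.051 for GABAergic interneuron markers, -0.0048 for cortical excitatory neuron markers, -0.038 for reactive astrocyte genes, -0.035 for mature oligodendrocyte markers, -0.068 for oligodendrocyte precursor markers, -0.026 for endothelial and pericyte markers and -0.058 for choroid plexus markers. The interneuron calcium buffer Pvalb was at -0.41 ± 0.13 and the neuropeptide precursor Tac1 at 0.73 ± 0.20, neither passing. Of the red blood cell genes Alas2 alone could be tested, at 0.08 ± 0.26 in RPF and 0.06 ± 0.14 in RNA.

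The second comparison asked how mRNA levels differed. The brain proline transporter gene Slc6a7 (chromosome 18, 60995380 to 61014222, GRCm38) rose from 67.5 and 69.5 CPM in the control RNA libraries to 198 and 169 CPM in the mutant ones, a log2 change of 1.42 ± 0.10 (SE, n = 2 per group). It was the 1 gene of 17361 to pass (edgeR, adjusted p = 0.0348), with 504 genes at an unadjusted p below 0.05 against 868 by chance. limma-voom called 1 gene and DESeq2 called 30, of which 22 were higher. Without control RNA library 1 the Slc6a7 change was 1.40 with adjusted p of 0.0779, and without control RNA library 2 it was 1.45 with adjusted p of 0.0533, so that 0 genes passed in each case. Without mutant RNA library 1, 78 genes passed, and without mutant RNA library 2, 124. Slc6a7 footprints were at 119 CPM in controls and 282 CPM in mutants, a log2 change of 1.24 ± 0.13 that did not pass over all genes (adjusted p = 0.115). Camk2a, the neighbouring kinase gene at 60925618 to 60988152 on the same chromosome, was at -0.12 ± 0.16 in RNA.

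**Figure D4:**
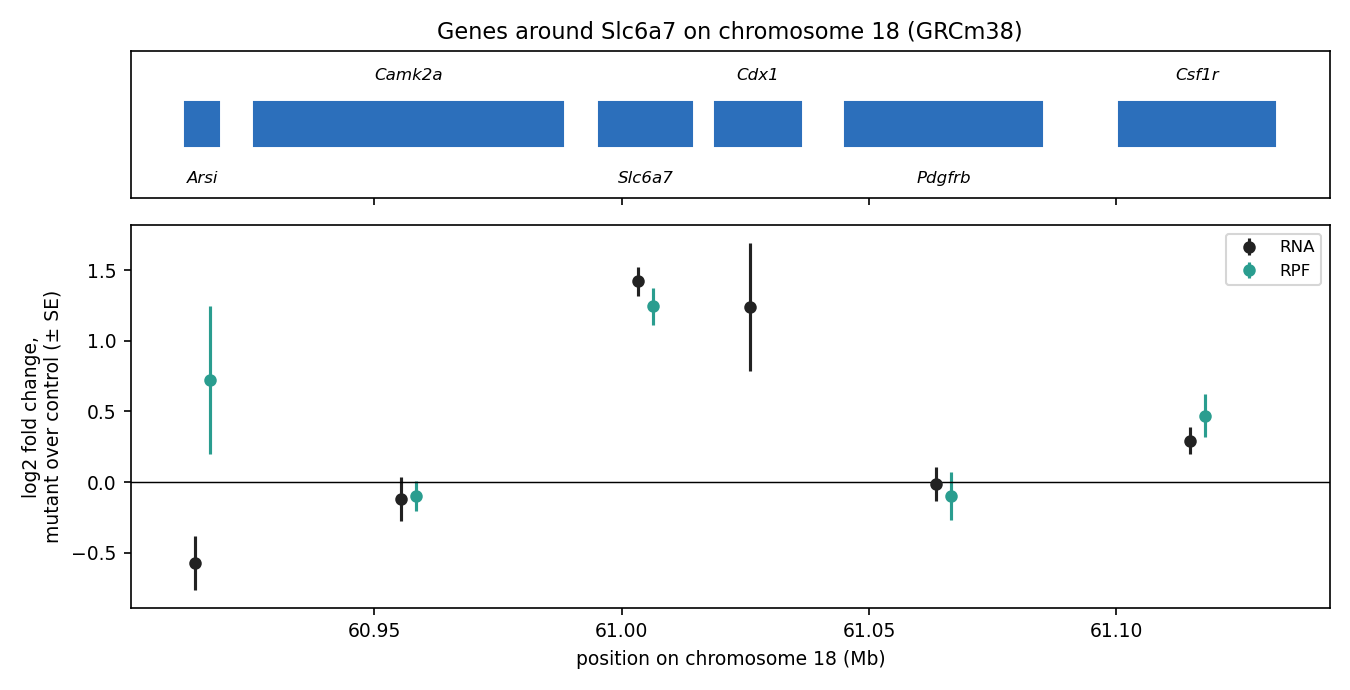
Map of genes around Slc6a7 on chromosome 18 (GRCm38) and the log2 fold change of mutant over control (± SE, n = 2 per group) of each in RNA (black) and RPF (teal). Slc6a7 is at 1.42 in RNA and 1.24 in RPF, and Camk2a at -0.12 in RNA.

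Selenoprotein mRNAs fell for 4 of 22 members when adjusted over the list alone, and 0 over all genes. Selenow (Sepw1) fell by 1.28 ± 0.13 on the log2 scale, from 119 to 48.8 CPM, Gpx1 fell by 0.94 ± 0.11, Selenoh (2700094K13Rik) fell by 1.56 ± 0.21 and Selenom (Selm) fell by 0.80 ± 0.15 (SE, n = 2 per group; edgeR, list-adjusted p from 0.000503 for Gpx1 to 0.0059 for Selm). Gpx3 at -1.04 ± 0.34 and Selenof (Sep15) at -0.30 ± 0.10 did not pass. Gpx4 mRNA was at -0.15 ± 0.14, and at 0.045 without mutant RNA library 1. Without mutant RNA library 2, 7 selenoproteins passed over the list alone. The whole list had a mean log2 change of -0.29 and a median of -0.037 (camera, adjusted p = 1.6e-09; adjusted p = 0.537 with an estimated correlation). Without Gpx1, Selenow and Selenoh the call was lost, with a median of -0.0013 (camera, adjusted p = 0.0899). The median of the whole list was -0.0053 without control RNA library 1, -0.13 without control RNA library 2, 0.0098 without mutant RNA library 1 and -0.082 without mutant RNA library 2. Genes with an early UGA had a median of -0.22 over 15 genes, 4 of which fell over that list alone (camera, adjusted p = 3.5e-14; adjusted p = 0.537 with an estimated correlation), and -0.36 with 7 passing without mutant RNA library 2. Those with the UGA close to the stop codon had a median of 0.0021 (adjusted p = 0.997), and the difference of means between the lists was -0.42 (exact permutation across genes, p = 0.0804).

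Microglia marker mRNAs were higher in mutant cortex for 20 of 20 genes, with a median log2 change of 0.43 (camera, adjusted p = 6.4e-25; adjusted p = 0.537 with an estimated correlation), and 10 rose when adjusted over the list alone, 0 over all genes. The lysosomal protease Ctss rose by 0.66 ± 0.12, Cx3cr1 by 0.53 ± 0.10 and Trem2 by 0.97 ± 0.24 (SE, n = 2 per group). Without control RNA library 2, 0 passed over the list alone, and 6 without mutant RNA library 2; the median was 0.67 without control RNA library 1. Of 12 reactive astrocyte genes, 4 rose over the list alone. The complement gene C4b rose by 0.79 ± 0.12 and the serpin Serpina3n by 1.03 ± 0.16. The intermediate filament Gfap rose by 1.25 ± 0.20 and the chemokine Cxcl10 by 2.84 ± 0.72. Cxcl10 had a mean count below 50 and ran from 2.24 to 4.01 across the alternatives. The list's median was 0.14 (camera, adjusted p = 1.4e-11; adjusted p = 0.537 with an estimated correlation), 0.37 without control RNA library 1 and 0.24 without mutant RNA library 1. Among 19 astrocyte markers Gfap and the water channel Aqp4, at 0.65 ± 0.11, rose over the list alone, and the median was 0.14 (camera, adjusted p = 4.5e-08; adjusted p = 0.682 with an estimated correlation). The astrocyte median was 0.071 without control RNA library 2, 0.069 without mutant RNA library 2 and 0.22 without control RNA library 1, and 4 genes passed without mutant RNA library 1. In RPF, Gfap was at 1.23 ± 0.56, C4b at 0.89 ± 0.29 and Serpina3n at 0.97 ± 0.43, none passing. The reactive astrocyte list as a whole did not rise in RPF. Of its 11 genes tested there, 5 had a higher estimate and 6 a lower one, with a median of -0.038.

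A further 11 lists had higher mRNA in mutants by the preset correlation, none holding with an estimated one (adjusted p = 0.880 with an estimated correlation for respiratory chain and histone genes, 0.803 for the others), and in none did a member pass over the list alone. Median log2 changes were 0.11 for NRF2 targets (camera, adjusted p = 0.000229; the cystine transporter Slc7a11 at 0.39 ± 0.11), and 0.10 for antioxidant enzymes without selenocysteine (0.000418; the peroxiredoxin Prdx6 at 0.38 ± 0.09). They were 0.063 for integrated stress response genes (0.000543, the transcription factor Atf3 at 1.53 ± 0.37 with a mean count below 50) and 0.12 for endoplasmic reticulum chaperones (0.000202). They were 0.10 for ribosomal proteins (2.8e-06), 0.043 for respiratory chain subunits (0.0105), 0.099 for histone genes (0.000469), 0.062 for small non-coding RNA genes (0.0015), 0.28 for meningeal fibroblast (0.0073), 0.22 for choroid plexus (0.0071) and 0.10 for striatal neuron markers (0.0071). Without control RNA library 2 the median was 0.057 for NRF2 targets, 0.051 for antioxidant enzymes, 0.028 for stress response genes, 0.0074 for ribosomal proteins, -0.020 for respiratory chain, 0.071 for histones, -0.044 for meningeal and 0.054 for choroid plexus markers, and each of these calls was lost. Without mutant RNA library 2 the calls were lost or turned for the same lists, at 0.060, 0.0017, 0.022, 0.022, -0.056, -0.077, -0.075 and 0.027, for endoplasmic reticulum chaperones at 0.034, and small non-coding RNA genes turned to -0.13. The striatal call was lost without control RNA library 1 (0.0039) or mutant RNA library 1 (0.12), and that of small non-coding RNA genes without control RNA library 1 (0.0098).

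The other way round, leaving out library 1 raised most of these medians. Without control RNA library 1 they were 0.17 for NRF2 targets, 0.16 for antioxidant enzymes, 0.20 for stress response genes, 0.19 for ribosomal proteins, 0.12 for respiratory chain, 0.17 for histones, 0.52 for meningeal and 0.35 for choroid plexus markers. Without mutant RNA library 1 they were 0.18, 0.20, 0.16, 0.17, 0.15, 0.27, 0.47 and 0.37 in the same order, 0.23 for endoplasmic reticulum chaperones and 0.34 for small non-coding RNA genes. Without control RNA library 2 the medians of striatal neuron markers and small non-coding RNA genes were higher, at 0.26 and 0.13. The 14 lists that did not pass in RNA (camera, adjusted p from 0.0501 to 0.997) included nonsense-mediated decay factors, 10 of 10 lower with a median of -0.11. Their other medians were -0.053 for synaptic genes, 0.031 for cholesterol synthesis, 0.030 for immediate early genes, -0.067 for thyroid hormone responsive genes and 0.025 for selenocysteine synthesis and incorporation factors. Cell-type medians were 0.048 for interneuron, -0.034 for excitatory neuron, 0.040 for oligodendrocyte, -0.020 for oligodendrocyte precursor, 0.050 for endothelial and pericyte, 0.063 for thalamic and -0.050 for dentate granule neuron markers.

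The third comparison asked whether footprints changed beyond mRNA, that is, whether translational efficiency (RPF relative to RNA) differed by genotype. Gpx4 efficiency was lower in mutants by a change of -1.002 ± 0.25 on the log2 scale (SE, n = 2 per group and assay), the 1 selenoprotein of 22 to pass over the list alone (edgeR interaction, list-adjusted p = 0.0499). Gpx1 was at -0.67 ± 0.22, Selenof (Sep15) at -0.38 ± 0.15, Selenot (Selt) at -0.38 ± 0.17, Selenow (Sepw1) at 0.36 ± 0.22, Secisbp2 at -0.12 ± 0.21 and Slc6a7 at -0.19 ± 0.18, none passing. The Gpx4 call was lost without control RPF library 1, either mutant RPF library, either control RNA library or mutant RNA library 2, and with RLE scaling, a mean count filter, non-robust estimation or limma-voom. Without control RPF library 2, 4 selenoproteins passed. Over all 17691 genes 0 passed, with 311 at an unadjusted p below 0.05 against 885 by chance; limma-voom called 0 and DESeq2 called 1, Snord12 (edgeR log2 change -1.31 ± 0.24). With the mouse as a block, 3 genes were called, all lower: Ptgds and Snord110 (adjusted p = 0.0466 each) and Snord55 (adjusted p = 0.0488), with unblocked values of -1.11 ± 0.46, -1.39 ± 0.35 and -1.39 ± 0.30; Snord110 was singled out after its values were seen. With the same block 2 selenoproteins passed over the list alone. Snord12, Snord55 and Snord110 are small non-coding RNAs, so their RPF to RNA ratio is no measure of translation.

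Selenoproteins had a median change in translational efficiency of -0.24 (camera, adjusted p = 0.0018; adjusted p = 0.995 with an estimated correlation), and those with an early UGA -0.31 (adjusted p = 0.0015; 0.995 with an estimated correlation). The selenoprotein call was lost without control RPF library 1 (-0.031), mutant RPF library 1 (-0.20) or mutant RNA library 2 (-0.28). It was also lost without both libraries of control mouse 1 (-0.091) or of mutant mouse 2 (-0.14), and the median was -0.13 without mutant RPF library 2. The early list lost its call without control RPF library 1 (-0.18), mutant RNA library 2 (-0.31) or mutant mouse 2 (-0.20). It stood at -0.15 without mutant RPF library 2 and -0.16 without control mouse 1. Late-UGA genes had a median of -0.021 (adjusted p = 0.408), and early and late means differed by -0.085 (exact permutation across genes, p = 0.658). Striatal neuron markers had a median of 0.41, 10 of 10 higher (camera, adjusted p = 1.1e-06; adjusted p = 0.995 with an estimated correlation), with Adora2a at 0.61 ± 0.25 and Penk at 0.57 ± 0.26, neither passing. Their call was lost without control RPF library 2 (0.31) or both libraries of control mouse 2 (0.17). The median was 0.23 without control RNA library 2 and 0.82 without control mouse 1. Meningeal fibroblast markers had a median of -0.92, 8 of 8 lower (adjusted p = 0.00024; 0.995 with an estimated correlation), with Slc6a13 at -0.93 ± 0.34. Their call was lost without control RPF library 1 (-0.33), mutant RPF library 1 (-0.43) or mutant RNA library 2 (-0.57), and the median was -1.39 without mutant RPF library 2. The mouse block added small non-coding RNA genes (median -0.057, camera, adjusted p = 0.0214) and thalamic neuron markers (-0.31, adjusted p = 0.0331), both lower. Both were lost with an estimated correlation (adjusted p = 0.980 with an estimated correlation). For non-coding RNAs the ratio is no measure of translation.

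The other 26 lists did not pass in translational efficiency without that block (camera, adjusted p from 0.0959 to 0.987), thalamic markers standing at -0.33 and small non-coding RNA genes at -0.14. Medians were -0.31 for dentate granule neuron, -0.29 for choroid plexus, 0.079 for microglia, -0.080 for astrocyte, -0.063 for oligodendrocyte, -0.025 for oligodendrocyte precursor, -0.036 for endothelial and pericyte, -0.025 for interneuron and 0.029 for excitatory neuron markers, and -0.14 for reactive astrocyte genes. They were -0.17 for selenocysteine synthesis and incorporation factors, -0.14 for antioxidant enzymes, -0.12 for histones, 0.097 for cholesterol synthesis, 0.087 for nonsense-mediated decay factors, 0.046 for endoplasmic reticulum chaperones, 0.043 for synaptic genes and 0.029 for ribosomal proteins. NRF2 targets stood at -0.031, stress response genes at -0.022, thyroid hormone responsive genes at -0.028, immediate early genes at -0.047 and respiratory chain subunits at -0.035. Cd74, the invariant chain of antigen presentation and a microglia list member, was at -1.10 ± 0.36 and did not pass.

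As a baseline, footprints were set against RNA in the control mice alone. Of 17691 genes 8003 differed (edgeR), 3812 with relatively more footprints and 4191 with fewer, as far as each library's own scaling allows. The part of each gene that was counted is not given in the sources used here; if untranslated regions were counted, genes with long ones have more RNA reads per footprint, so ratios of different genes are not footprints per mRNA alone. With the mouse as a block 8622 differed, 4132 with more and 4490 with fewer; 7886 genes were called in both fits and 117 lost their call. Selenoproteins had a median log2 ratio of -0.51 (camera, adjusted p = 0.0144; adjusted p = 0.978 with an estimated correlation), 2 of 22 higher and 10 lower over all genes and 2 and 11 adjusted over the list alone. With the block 2 were higher and 12 lower both over all genes and over the list alone, Gpx1 and Gpx3 being called over all genes in that fit alone. The deiodinase Dio2 at -2.71 ± 0.14, Selenot (Selt) at -2.45 ± 0.12, Selenow (Sepw1) at -1.17 ± 0.16 and Selenof (Sep15) at -0.87 ± 0.11 (SE, n = 2 per assay) had fewer footprint counts relative to RNA counts. Txnrd2 at 0.68 ± 0.17 and Selenon (Sepn1) at 0.57 ± 0.20 had more. Genes with an early UGA had a median of -0.87 (camera, adjusted p = 0.0021) and the late list 0.053 (adjusted p = 0.871), a difference of means of -0.75 (exact permutation across genes, p = 0.0636). Ribosomal protein mRNAs had a median of -0.95 (adjusted p = 2.2e-08), respiratory chain subunits 0.46 (4.1e-06), histones 0.79 (3.8e-06), synaptic genes 0.19 (0.0244) and interneuron markers 0.39 (0.0158). Replication-dependent histone mRNAs largely lack poly(A) tails, so poly(A) RNA understates them and their ratio is no measure of translation. None of these list calls held with an estimated correlation (adjusted p = 0.978 with an estimated correlation), and the other 23 lists did not pass with the preset one (adjusted p from 0.0629 to 0.967). Taken alone and not against other genes (fry), 9 lists passed: selenoproteins, early-UGA genes and ribosomal proteins with fewer footprints, and endoplasmic reticulum chaperones, cholesterol synthesis and interneuron markers with more (adjusted p = 0.0119 each). The others, also with more, were nonsense-mediated decay factors (adjusted p = 0.0361), and respiratory chain subunits and selenocysteine factors (adjusted p = 0.0481 each). With the mouse as a block and the preset correlation 4 of the 23 lists passed, all with more footprints: meningeal fibroblast markers (median 0.996, adjusted p = 0.0160), endoplasmic reticulum chaperones (0.51, adjusted p = 0.0227), antioxidant enzymes (0.28, adjusted p = 0.0417) and NRF2 targets (0.64, adjusted p = 0.0470). In the blocked fit too none passed with an estimated correlation (adjusted p = 0.736 for chaperones and 0.804 for the other 3, with an estimated correlation).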

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

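The matched-list comparisons for microglia and selenoproteins were set down before their results were seen. Leaving out one library was planned for selenoproteins and for single genes, but was turned to weighing an explanation afterwards, and the other tests of a technical or tissue explanation, leaving out one library for microglia markers included, were chosen afterwards. With 2 libraries per group, no test for a library standing apart from its group was run.

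In 4 gene lists the genotype effect differed between footprints and RNA by the interaction test with the preset correlation. Median differences were -0.2414 for selenoproteins, -0.3072 for those with an early UGA, -0.9194 for meningeal fibroblast markers and 0.411 for striatal neuron markers, and each was lost with an estimated correlation (camera, adjusted p = 0.995 with an estimated correlation for each). Per mouse, the median log2 ratio of RPF to RNA over selenoproteins was -0.40 and -0.64 in controls and -0.64 and -0.70 in mutants, and over early-UGA genes -0.89 and -0.84 in controls and -0.75 and -1.05 in mutants, so the genotypes met or overlapped. Over meningeal markers it was 1.09 and 0.74 in controls and 0.22 and 0.63 in mutants, and over striatal markers 0.13 and -0.49 in controls and 0.20 and 0.36 in mutants.

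Lower selenoprotein footprints, with a median log2 change of -0.32, were weighed first. A bias against short or weakly expressed genes is argued against, since 0 percent of 10000 lists matched on coding length and expression had a median as low, the middle 95 percent of those lists running from -0.0974 to 0.107. One deviating library as the whole cause is argued against too, as the highest median on leaving out one RPF library was -0.2316. The call for the full list rests on the preset correlation and was lost with an estimated one (camera, adjusted p = 0.486). Leaving out libraries therefore speaks to the direction and not to that call. Lower mRNA as the whole cause stays open: the median in translational efficiency was -0.2414, but leaving out control RPF library 1 (-0.031), mutant RPF library 1 (-0.20) or mutant RNA library 2 (-0.28) ended that call. An effect of the Secisbp2 alleles on decoding, the explanation the design names, may contribute, but Cre status goes with genotype and keeps this a hypothesis.

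Higher microglia markers in RNA, with a mean log2 change of 0.4712 over 20 genes, were weighed next: a lower share of other cells would raise all remaining cell types alike, yet oligodendrocyte, precursor and endothelial markers had a mean of 0.0282 over 47 genes, a difference of 0.4431 (permutation across genes, two-sided p = 1e-05, the smallest that 100000 relabellings give). Astrocyte, meningeal and choroid plexus markers, with means of 0.211, 0.247 and 0.174, were also higher in RNA. With them added the mean was 0.109 over 86 genes and the difference 0.362 (permutation across genes, p = 1e-05). Genes are not independent replicates, so both p-values leave out variation between mice. A single deviating library as the whole cause is argued against, since the lowest median on leaving out one RNA library was 0.3174. The call for the full list was lost with an estimated correlation (camera, adjusted p = 0.537), so this speaks to the direction alone. Whether there were more microglia of the same kind or a change within microglia cannot be told apart: the spread of the members' changes exceeded that of 91.65 percent of lists matched on expression, inside the middle 95 percent, while the myeloid genes Itgax, Cst7 and Clec7a, outside that list, stood at 2.46 ± 0.32, 2.32 ± 0.33 and 2.81 ± 0.46 in RNA, against more microglia of the same kind alone but picked for small p or after their values were seen. Cst7 and Clec7a had mean counts below 50 in RNA. An effect of genotype or of Cre may underlie either more microglia or a change within them.

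For Slc6a7, at 1.42 in RNA, more excitatory neurons in the tissue is argued against, as the highest of the 20 excitatory neuron markers stood at 0.3349. A single deviating library is argued against, as the lowest change on leaving out one RNA library was 1.309, although without control RNA library 1 or 2 the Slc6a7 change was 1.40 ± 0.16 and 1.45 ± 0.16, its adjusted p rose to 0.0779 and 0.0533 with the wider error, and the call was lost. A candidate explanation is extra copies of the stretch beside Camk2a carried with the Cre transgene, which would raise RNA and footprints alike. The change in translational efficiency was -0.1892 ± 0.18. Any other cause of higher Slc6a7 mRNA could leave that ratio unchanged too, so the value does not single out extra copies. The nearest other gene Cdx1, at 1.24 ± 0.45 in RNA, had only 8 to 24 counts per library and was singled out after its values were seen, and Pdgfrb, 30.9 kb from Slc6a7 on the same side and also looked up afterwards, was at -0.016 ± 0.12 in RNA and -0.097 ± 0.17 in RPF, against a stretch reaching that far but not a shorter one. This stays open, since the labels do not give the makeup of the transgene and Cre and genotype went together.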

How the results depend on the processing

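Most alternatives were fixed before the data were examined; the crossed pairing, the omission of both libraries of a mouse, and all alternatives for lists other than the selenoproteins, for counts over a list alone and for lists in the control ratio were chosen after seeing the data. For 47 results on lists and counts, 277 of 412 alternative values kept direction and side of the threshold or stayed close for counts; for named genes, 1294 of 1435 did. Counts of calls moved most. In RPF 0 genes became 38 without a filter, 25 with DESeq2 and 2 in the joint fit of 8 libraries, and 7 to 21 on leaving out one library. In RNA 1 became 11 without a filter, 30 with DESeq2 and 25 with the replicate number as a block, and 0 to 124 on leaving out one library. In translational efficiency 0 became 1 with DESeq2 and 3 with the mouse as a block, and 0 to 3 on leaving out one library or mouse. Replicate numbers mark different mice across genotypes, and differences between replicates correlated at -0.287 in RPF and -0.240 in RNA; crossing the numbers in the block gave 30 and 41 calls. The RPF count stayed at 0 with the replicate number as a block, while the selenoproteins passing over the list alone in RPF went from 8 to 5. The mouse block gave 8622 calls in the control ratio. Calls it changed are given with the efficiency and control results.

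The selenoprotein medians of -0.32 in RPF, -0.037 in RNA and -0.24 in translational efficiency lost their calls with an estimated correlation (adjusted p = 0.486, 0.537 and 0.995) and with fry (adjusted p = 0.386, 0.686 and 0.972). Without Gpx1, Selenow and Selenoh the RNA median was -0.0013 (adjusted p = 0.0899). Leaving out one library gave medians from -0.59 to -0.23 in RPF, -0.13 to 0.0098 in RNA and -0.30 to -0.031 in efficiency. The early minus late difference of -0.56 in RPF was -0.42 in RNA and -0.085 in efficiency, neither past the threshold.

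On leaving out one library these lists changed sign: in RPF small non-coding RNA genes (-0.51 to 0.32), astrocyte markers (-0.051 to 0.31) and meningeal markers (-1.18 to 0.073), and in RNA respiratory chain subunits (-0.056 to 0.15), histones (-0.077 to 0.27), small non-coding RNA genes (-0.13 to 0.34) and meningeal markers (-0.075 to 0.52). So did single genes without a call: Gpx4 (-0.36 to 0.045) and Camk2a (-0.29 to 0.095) in RNA, Pdgfrb in RNA (-0.15 to 0.12, and 0.0028 in the joint fit) and RPF (-0.27 to 0.099), Txnrd1 in RPF (-0.20 to 0.26, and -0.0285 with library totals and -0.0010 with the mean count filter) and in RNA (-0.050 to 0.079), and Secisbp2 in efficiency (-0.29 to 0.060). The cause was not tested. No scaling moved the median of all genes by 0.1. The control RPF libraries, at 7888685 and 9761127 counts, are the shallowest of the 8.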

Other observations

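Most genes in these paragraphs were named by the fixed rule as those with the smallest p in their direction or list; Cst7, Clec7a, Lyz2 in RNA, Csf1r and Arsi were chosen after their values were seen. None passed over all genes in the edgeR test of the report, so they are given as values. Some passed under alternatives: Itgax, Mpeg1, Syt2 and Capn5 in RNA did so with edgeR without a filter, with edgeR and the replicate number as a block, and with DESeq2.

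In RNA the integrin Itgax was at 0.867 CPM in controls and 4.77 CPM in mutants, a log2 change of 2.46 ± 0.32 (SE, n = 2 per group). The cystatin Cst7 was at 2.32 ± 0.33 and the lectin receptor Clec7a at 2.81 ± 0.46, both with mean counts below 50. The pore-forming Mpeg1 was at 1.13 ± 0.14 and the lysozyme Lyz2 at 1.28 ± 0.30. In RPF Mpeg1 was at 1.28 ± 0.22, Lyz2 at 1.38 ± 0.23 and the microglial receptor Gpr34 at 1.35 ± 0.21. Across the alternatives Itgax in RNA ran from 2.04 to 2.78 and Mpeg1 from 0.98 to 1.31. The colony-stimulating factor receptor Csf1r, a microglia gene that lies 86.4 kb from Slc6a7, was at 0.29 ± 0.10 in RNA, and Arsi, on the far side of Camk2a, at -0.57 ± 0.19.

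Among neuronal genes the synaptotagmin Syt2, a calcium sensor of fast release, was at 1.02 ± 0.15 in RPF and 0.77 ± 0.11 in RNA. The calpain Capn5 was at -0.96 ± 0.15 in RPF and -1.004 ± 0.11 in RNA, 49.9% of control. The interneuron markers Pvalb and Lhx6 were at -0.36 ± 0.15 and -0.47 ± 0.17 in RNA, while Tac1 was at 0.37 ± 0.09. Of the 23 interneuron markers 14 were higher in RNA and 9 lower, with a median of 0.048. The deep-layer transcription factor Fezf2 was at -0.55 ± 0.15. Drd1 and Penk, higher in footprints, were at 0.37 ± 0.11 and 0.32 ± 0.10 in RNA. In translational efficiency Slc35d3 was at 1.16 ± 0.32, Nexn at 1.00 ± 0.28 and the small nucleolar RNA Snord66 at -1.42 ± 0.29. Snord66 is non-coding, so its ratio is no measure of translation.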
